A study of Mus musculus with 4 samples.

How the data were processed

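The study measured total RNA of V6.5 mouse embryonic stem cells, a widely used pluripotent line, by RNA-seq after transfection with a short hairpin against GFP (shGFP, 2 libraries) or against NCAPH2, a subunit of the condensin II complex (shNCAPH2, 2 libraries). Per the labels' protocols, cells were at passage 3, were selected for 5 days with puromycin at 2 µg/mL, and were taken off feeder fibroblasts before harvest. RNA was treated with DNase I, depleted of ribosomal RNA and made into libraries with an Illumina kit, and the labels do not say whether the kit or the counting kept the strand of a read. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

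The authors deposited 1 table of raw counts per library. The submitters' processing notes name TopHat2 2.0.10, edgeR (version not given) and the build mm9, without saying what each was used for. The start and end positions in the tables nevertheless followed GRCm38: of 1517 features with a symbol, 1465 matched a gene of the same symbol and place in the GENCODE annotation of that build, and 1275 had the same start or end. Coordinates below are those of the tables and are named as GRCm38. The annotation used for counting is not given in the sources used here.

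All 4 tables held the same 1618 rows. The 101 rows without a symbol held 22.2% to 23.3% of the counts of a library and were kept out of library sizes and tests. Counts in the 1517 named features summed to 507891 and 429907 in the shGFP libraries and to 243628 and 272426 in the shNCAPH2 libraries. Each named feature, and each of the 101 other rows, had a lower summed count in shNCAPH2 than in shGFP, and none kept more than 67.8% of its shGFP count. The tables therefore hold a part of each library that goes with the outcome. Their sums are not sequencing depths, and no library totals were used here. Ncaph2 was not analysed here, so the knockdown could not be checked on its own transcript.

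Counts as deposited were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr at its defaults and a model of group alone, which left 896 features and 2 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Since TMM was computed over the 896 tested features, all lower in shNCAPH2, a fold change is relative to the typical tested feature. A value of 0 means about the median loss of tested features (their median was -0.004), and a positive value a smaller loss. It does not mean the median loss of all named features, who kept a median of 46.7% of their shGFP count. Slc7a11, for example, kept 47.3% and had a value of -0.25. Scaling all libraries to an equal size, added after seeing the data, moved the median log2 fold change to -0.84, and neither scaling is known to be right. Gene lists with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation of 0.01, two-sided), in 1 family of 10 tests with 4 quartiles of local gene density. Density was the number of coding genes starting within 500000 bases on either side. The exact interval given for a ratio of counts covers counting error only. A ± beside counts is an SD between libraries. A ± beside a fold change is a standard error (SE) derived from the test. It is the absolute log2 fold change divided by the square root of the F statistic.

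On simulated counts for the same 896 features, with 200 changed by known folds, the test recovered 22% of features lowered 2-fold, 86% of those lowered 4-fold, 50% of those raised 2-fold and 96% of those raised 4-fold, with 2 false calls among 696 unchanged features. The simulation gave every feature a common dispersion and applied no selection on the outcome. In the listed features the highest relative log2 fold change was 0.26, so rises of 2-fold or 4-fold did not occur. The rates therefore describe the test on unselected counts only. Of 31 gene lists, 6 had enough tested members for camera. The lists, the tests and the rule for named genes were set before the data were examined. The rule named Ncaph2, other tested condensin subunits, up to 12 features per direction with the largest fold change past the threshold (mean logCPM of at least 1, groups not overlapping, gene models without a name left out), and up to 4 tested members of each list with the smallest p. Of the features so named or listed, 4 are not reported here, 1 of them among the 9 past the threshold.

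Alternatives were RLE size factors, no filter on low counts, a stricter filter, a replicate block, leaving out each library, DESeq2 1.42.0, edgeR's exact test, limma voom, a minimum fold of 1.2, thresholds of 0.01 and 0.1, fry, an estimated correlation and a window of 100000 bases. Equal library sizes, a crossed pairing of the replicate numbers, and features without an exon of an opposite-strand gene were added after seeing the data. Permutation and exact tests used scipy 1.17.1.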

Results

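RNA-seq counts were compared between V6.5 mouse embryonic stem cells carrying a short hairpin against NCAPH2 (2 libraries) and cells carrying one against GFP (2 libraries). NCAPH2 is a subunit of condensin II, a complex that organises chromosomes. The tables gave counts for 1517 named features, of which 1155 matched annotated protein-coding genes. Summed over these features, the shGFP libraries held 507891 and 429907 counts and the shNCAPH2 libraries 243628 and 272426. Ncaph2 was not analysed here. Of the other condensin subunits, Ncapd3, a condensin II subunit, had 8 and 11 counts in shGFP and 4 and 3 in shNCAPH2. These were too few to be tested in the main fit. Without a filter on low counts Ncapd3 did not pass (relative log2 fold change -0.49 ± 0.68 SE, edgeR adjusted p = 0.85).

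Every named feature had fewer summed counts in shNCAPH2 than in shGFP. The median feature kept 46.7% of its shGFP count and the highest kept 67.8%. Both shNCAPH2 counts lay below both shGFP counts in 1341 features (88.4%), and 97 features had no count in either shNCAPH2 library. Because no feature above 67.8% was listed, the direction is a property of the list and is not independent evidence of a loss. The counts were low, with a median of 35.0 summed over the shGFP libraries and 922 features under 50. Exons of 636 features (41.9%), among them Ccna2, Ccne2 and Pou5f1, overlapped an exon on the opposite strand, and the labels do not state whether strand was kept, so counts of these features may include reads of the overlapping gene. If reads were counted on the other strand, the counts of every feature, named below or not, would be of antisense reads.

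**Figure D1:**
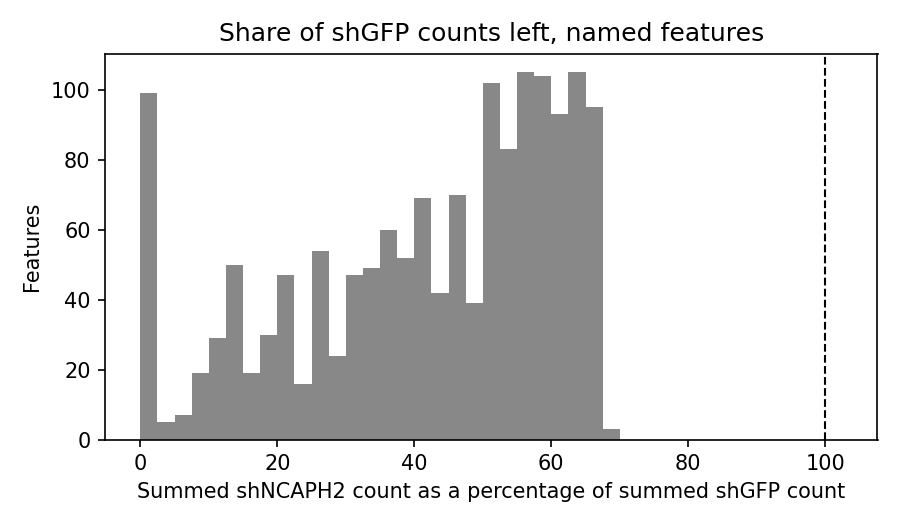
Histogram of the 1517 named features by summed shNCAPH2 count as a percentage of summed shGFP count (x axis, percent; y axis, number of features; dashed line, equal sums). The features end at 67.8%, with none near or above the line.

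Relative to the typical tested feature, 9 of 896 tested features fell further in shNCAPH2 and 0 fell less. The threshold was an adjusted p under 0.05 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). As no feature above 67.8% was listed, the highest relative log2 fold change was 0.26, and the list left little room for a higher call. At an unadjusted p under 0.05 there were 57 lower and 0 higher, against 66 and 20 with the replicate numbers crossed between groups, 66 and 7 without shNCAPH2 replicate 1, 37 and 6 with DESeq2, and 51 and 4 without shGFP replicate 1. Frmd8, which binds the iRhom proteins (chromosome 19, 5849702 to 5875274, GRCm38), went from 89.0 ± 9.90 counts in shGFP to 7.5 ± 2.12 in shNCAPH2 (SD, n = 2 each), a relative log2 fold change of -2.73 ± 0.36 (SE, edgeR adjusted p = 0.0050). Fxyd4, a regulator of the sodium-potassium pump (chromosome 6, 117933729 to 117937335), went from 52.0 ± 5.66 to 2.0 ± 1.41 counts (-3.83 ± 0.54, edgeR adjusted p = 0.0060).

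Col23a1, a transmembrane collagen, fell from 107.5 ± 7.78 to 17.0 ± 2.83 counts, and Ndrg4 from 72.0 ± 18.4 to 10.5 ± 3.54, with relative log2 fold changes of -1.83 ± 0.30 and -1.94 ± 0.35 (edgeR adjusted p = 0.017 and 0.028). The pseudogene Best4-ps fell from 101.5 ± 0.71 to 11.5 ± 10.6 counts (-2.33 ± 0.46, edgeR adjusted p = 0.042). Nrbf2, an autophagy factor, had 22 and 21 counts in shGFP against 0 and 1 in shNCAPH2, a relative log2 fold change of -4.38 ± 0.81 (edgeR adjusted p = 0.031); the ratio of its counts without scaling was 43.0, with an exact 95% interval of 7.32 to 1737. It was past the threshold with all 4 libraries and not without shGFP replicate 1 (adjusted p = 0.17) or shGFP replicate 2 (0.13). Col23a1 likewise did not pass without shNCAPH2 replicate 2 (adjusted p = 0.071), and Best4-ps and Ndrg4 were among 4 of the 8 features named here that did not pass with a replicate block. The exons of Frmd8 overlapped those of Frmd8os on the opposite strand, so its count is uncertain where reads were counted without strand.

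A further pair, chosen after their values were seen because they fall outside the rule for named genes, were the pseudogene 6820431F20Rik and the gene model Gm12913. For 6820431F20Rik the counts were 241 and 193 in shGFP and 37 and 44 in shNCAPH2 (-1.59 ± 0.21, edgeR adjusted p = 0.0050). Gm12913 had 4205 and 1098 counts in shGFP, which differed more from each other than in any other called feature, and 51 and 67 in shNCAPH2 (-4.59 ± 0.48, edgeR adjusted p = 0.0016). The count of 9 was 14 without shGFP replicate 1, 18 without shGFP replicate 2, 16 without shNCAPH2 replicate 1, 12 without shNCAPH2 replicate 2, 4 with a replicate block, and 284 lower and 0 higher among 928 features when all libraries were given an equal size. Of the 8 named, 7 (all but Frmd8) had no opposite-strand exon. In a fit of the 431 tested features without one, Fxyd4 and Gm12913 passed and the other 5 did not (adjusted p = 0.070 to 0.13), though all 7 kept at least 93.5% of their log2 fold change.

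**Figure D2:**
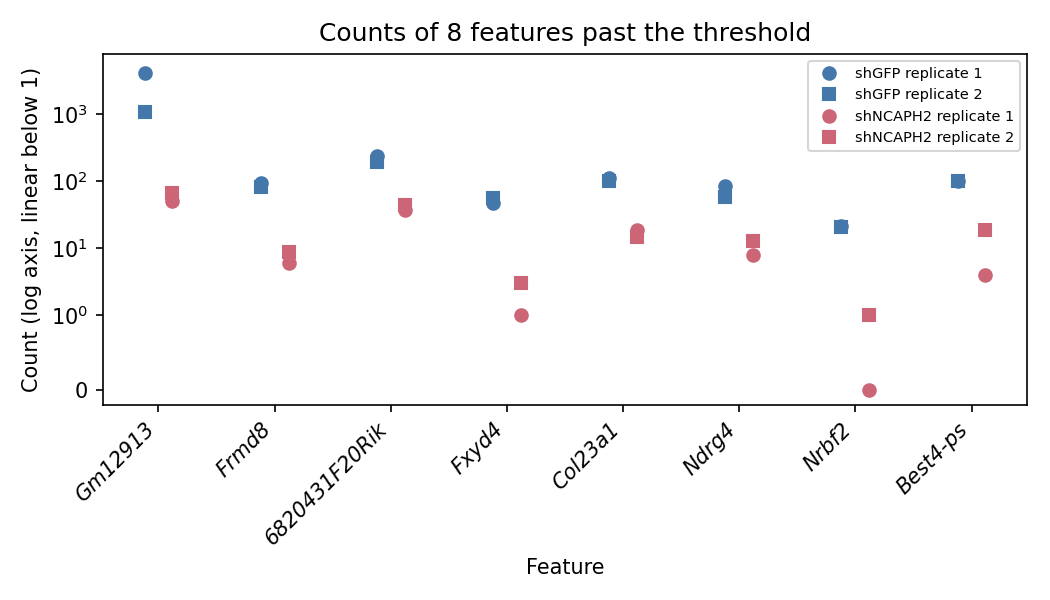
Counts of 8 of the 9 features past the threshold (x axis) in each library (y axis, deposited count on a log axis that is linear below 1; circles, replicate 1; squares, replicate 2; blue, shGFP; red, shNCAPH2). In each of the 8 both shNCAPH2 points lie below both shGFP points, and Nrbf2 reaches 0 in shNCAPH2 replicate 1.

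A smaller loss of replication-dependent histone genes, which are transcribed in S phase, than of other tested features passed in camera with the preset correlation and not with an estimated one. Of 68 annotated members 36 were listed and tested, and in the main fit none was called singly, over all genes or adjusted over the list alone. With equal library sizes 3 were called lower and 0 higher over all genes. Their median relative log2 fold change was 0.12 (camera adjusted p = 0.019, or adjusted p = 0.86 with an estimated correlation), and -0.72 with equal library sizes. The 36 members had high counts, with a median of 141.0 for the mean shGFP count. Over all named features the median was 35.0 for the shGFP count summed over both libraries. Whether the smaller loss goes with count level was not tested. Hist1h1c, a linker histone, had 237 and 160 counts in shGFP and 131 and 128 in shNCAPH2 (0.23 ± 0.19 SE), and Hist1h2ae had 248 and 158 against 121 and 145 (0.23 ± 0.19). Hist2h2bb lay the other way, at -0.49 ± 0.35. Of the 36 members, 15 had an exon that overlapped an opposite-strand exon, among them Hist1h2ae (Gm44394) and Hist2h2bb (Gm20628). The list did not pass without shGFP replicate 2 (median -0.05, adjusted p = 0.86) or without shNCAPH2 replicate 2 (adjusted p = 0.12). Histone genes of a cluster are near copies, and Hist1h2bq and Hist1h2br had the same 4 counts, so reads may have been shared between them. Other members had nearly the same counts. Hist1h2ac had 240 and 160 in shGFP and 120 and 138 in shNCAPH2, and Hist1h2ag had 243 and 162 against 120 and 141.

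Of 91 annotated ribosomal protein genes 30 were listed and 28 tested, none called. Their median relative log2 fold change was 0.07 (camera adjusted p = 0.18). Rpl26 had 188 and 109 counts in shGFP and 91 and 106 in shNCAPH2, and Rpl8 had 32 and 26 against 14 and 12. Of 25 ribosome biogenesis genes 10 were listed and 8 tested (median -0.09, camera adjusted p = 0.999, test direction up), with Ncl, the nucleolar protein nucleolin, at 205 and 130 against 115 and 86 counts. The 5 listed heat shock genes of 14, all chaperones, had a median of -0.34 (camera adjusted p = 0.38). Hsp90aa1 had 559 and 342 against 212 and 155 counts (-0.44 ± 0.24).

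The naive pluripotency list, of genes tied to the embryonic stem cell state, had 6 of 30 members listed and 5 tested. None was called, and the median was 0.13 with a mean of -0.14 (camera adjusted p = 0.999, test direction down). Without 1 library the median was negative each time (-0.28 to -0.06). The filter was applied anew each time, so the members could differ, with 6 tested without shNCAPH2 replicate 1. The transcription factor Nanog had 2114 and 2345 counts in shGFP against 1530 and 1243 in shNCAPH2 (0.13 ± 0.22). With equal library sizes its value was -0.69 and past the threshold (edgeR adjusted p = 0.040). Under that scaling 284 features passed as lower and 0 as higher, in a list with none above 67.8%. Passing under it, here and below, is therefore not independent evidence of a loss. Pou5f1, which encodes OCT4, had 39 and 21 counts against 12 and 9 (-0.67 ± 0.40), and its exons overlap those of Gm19553. Zfp42 had 59 and 35 against 19 and 19 (-0.46 ± 0.32). Sox2, at 36 and 18 against 16 and 17 counts (0.13 ± 0.37), lay the other way. So did Trim28, at 32 and 16 against 12 and 18 (0.16 ± 0.39). Esrrb, named after its values were seen, had 11 and 13 against 0 and 1 and was below the filter of the main fit. It did not pass without a filter (relative log2 fold change -3.44 ± 1.02, edgeR adjusted p = 0.077) and passed with equal library sizes, whose filter kept it (-4.28 ± 0.67, edgeR adjusted p = 0.029). Of 28 mitosis genes 6 were listed and 5 tested (median 0.07, camera adjusted p = 0.47), with Ccna2, cyclin A2, at 610 and 558 against 315 and 379 counts (0.06 ± 0.19, or -0.75 with equal library sizes, edgeR adjusted p = 0.040).

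The other lists had fewer than 5 tested members and, in the main fit, no member past the threshold over all genes. With equal library sizes, where no feature was called higher, some members passed as lower. Among them were Polr3e, Slc7a11, Egr1, Pkm, Ccne2, Rad52 and Igfbp7 (edgeR adjusted p of 0.029 to 0.048). None of the 4 tested cohesin and loop genes did. Egr1, an immediate early transcription factor, had 42 and 36 counts in shGFP against 0 and 5 in shNCAPH2 (-3.10 ± 0.63, edgeR adjusted p = 0.051), and passed when adjusted over the list alone, where 2 of 17 members were listed. Polr3e, a subunit of RNA polymerase III, had 21 and 16 against 2 and 3 counts (-2.02 ± 0.55, edgeR adjusted p = 0.15) and passed over its list alone, as the 1 tested of 4 listed members among 21. Slc7a11, a cystine transporter, 1 of 2 listed stress response genes of 24, had 5780 and 4559 counts against 2217 and 2674 (-0.25 ± 0.18). Pkm, a glycolytic enzyme in a list with 6 of 24 members listed, had 140 and 83 against 44 and 36 counts (edgeR adjusted p = 0.79).

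Cohesin and loop genes had 7 of 19 members listed and 4 tested, from Smc1a at 0.16 ± 0.38 to Smc3 at 0.22 ± 0.41. DNA replication had 5 of 29 listed (Ccne2, 0.11 ± 0.18), Polycomb and DNA methylation 5 of 26 (Ezh2, -0.14 ± 0.40), DNA repair 3 of 27 (Rad52, -0.45 ± 0.35), formative genes 3 of 19 (Dnmt3b, -0.59 ± 0.65), and variant histones 2 of 11 (H2afx, 0.16 ± 0.26). Of small noncoding RNA genes 3 of 355 were listed, among them Rn7sk (-0.26 ± 0.28). Of fibroblast genes, which mark the feeder cells, 3 of 30 were listed, with Igfbp7 at 58 and 65 against 32 and 29 counts. Exons of Igfbp7 overlap those of Polr2b on the opposite strand, so its counts may include reads of that gene. P53 targets had 2 of 25 listed, and the mesoderm and endoderm, neuroectoderm, 2-cell and protocadherin lists 1 each (Mixl1, Stmn2, Eif1a and Pcdhb17), none tested in the main fit. Trophectoderm, Hox, imprinted, germline and mitochondrial or nuclear retained RNA lists had 0 members listed.

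Features were then grouped by the number of coding genes that start within 500000 bases of their own start, since condensin II acts on chromosome structure. The sparsest quartile (0 to 9 neighbours, 250 features) had a median relative log2 fold change of -0.07, and the densest (30 to 69 neighbours, 222 features) one of 0.03. Neither passed (camera adjusted p = 0.10 for both), and the quartiles between had medians of -0.01 and 0.01. The quartiles held 4, 2, 2 and 1 of the called features. Without shNCAPH2 replicate 1 both outer quartiles passed (adjusted p = 0.047), and with a window of 100000 bases the densest passed (adjusted p = 0.042). With an estimated correlation neither outer quartile passed, whether with all libraries (adjusted p = 0.86), without shNCAPH2 replicate 1 (0.67) or with the smaller window (0.23).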

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

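Equal library sizes, the crossed pairing of replicate numbers, the restriction to features without an opposite-strand exon, an estimated correlation in other settings and the split of the simulation by count were chosen after the data were seen. No alternative called a feature higher. In the 14 alternatives with values per gene, the 8 called features reported by name kept a negative value wherever they were tested, and Frmd8, Fxyd4 and Gm12913 passed wherever tested, Frmd8 not being in the restricted set. Nrbf2, Ndrg4, Best4-ps, Col23a1 and 6820431F20Rik each lost the call in at least 1, with adjusted p of up to 0.79, 0.14, 0.13, 0.071 and 0.070. The count was 16 with RLE size factors, 21 without a filter, 16 with the stricter filter, 22 with the exact test, 6 with DESeq2, 7 with limma voom, 9 at a fold of 1.2 or more, 4 at an adjusted p under 0.01 and 19 under 0.1. It was 284 with equal library sizes, 2 among the features without an opposite-strand exon (431 tested), and 12 to 18 without 1 library; the cause was not tested. That restricted set held 7 of the 8 called features reported by name. Fxyd4 and Gm12913 passed in it, and 5 lost the call with little change in fold: Nrbf2 went from -4.38 ± 0.81 to -4.28 ± 0.83 (SE), Best4-ps from -2.33 ± 0.46 to -2.23 ± 0.54, Ndrg4 from -1.94 ± 0.35 to -1.83 ± 0.33, Col23a1 from -1.83 ± 0.30 to -1.73 ± 0.33 and 6820431F20Rik from -1.59 ± 0.21 to -1.49 ± 0.27. With fewer features the prior degrees of freedom fell from 8.30 to 5.39, and the biological coefficient of variation rose from 0.20 to 0.26. A fit with a replicate block gave 4. Whether same-numbered libraries shared a day or batch is not given, and a correlation cannot exclude it. Their deviations showed no positive correlation: r was -0.06 over the 896 tested features, and -0.64 over the 243 with 300 or more summed shGFP counts. The second value led to a fit with the numbers crossed, which called 9 features, 6 of them among the main 9. Among lists, 1 passed with the preset correlation, 0 with an estimated one, 0 with fry, 2 without a filter, 2 with equal library sizes, 2 in the restricted set, and 0 to 3 without 1 library. Of the density quartiles 0 passed, against 1 with a window of 100000 bases and 0 to 2 without 1 library; the cause was not tested. The block changed no list or quartile call. Ncaph2 gave no value in any setting, and pseudocounts were not run because the tables hold counts.

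Of the named genes' values under alternatives, 672 kept their direction and side of the threshold, 18 passed newly, 19 no longer passed and 71 changed sign, none of the latter past the threshold in the main test and 3 past it under the alternative (Ccne2, Ccna2 and Nanog with equal library sizes). A sign change under equal library sizes follows from the shift of the median to -0.84: Smc3 -0.62, Ctcf -0.63, Sgol1 -0.63, Smc1a -0.67, Ccne2 -0.71, Mcm10 -0.63, Kif20a -0.61, Ccna2 -0.75, Incenp -0.71, Nanog -0.69, Trim28 -0.67, Ncl -0.74, Eed -0.70, Hist1h1c -0.62, Hist1h2ae -0.61, Hist1h2ac -0.63, Rpl26 -0.59, H2afx -0.68. The test direction of density quartile 3 (median -0.83 there) also turned, for a cause that was not tested. Other sign changes, whose cause was not tested, were Dnmt1 0.0171, Cbx1 0.0563 with RLE; Aldoa 0.0345, Dnmt1 0.0761, Cbx1 0.11 without a filter; Cbx1 0.0337 with the stricter filter; Cbx1 0.00243 with the replicate block; Aldoa 0.12, Ezh2 0.0351, Dnmt1 0.14, Cbx1 0.18, Rpph1 0.0663 with DESeq2; Cbx1 0.00957 with limma voom; Dnmt1 0.0593, Cbx1 0.10 in the restricted set; and the ribosome biogenesis list -0.0866 with fry. Ranges without 1 library, where the lone library of a group was taken to vary like the others, were Mcm10 -0.11 to 0.52, Aldoa -0.37 to 0.34, Hspd1 -0.64 to 0.0303, Ccna2 -0.00258 to 0.17, Nanog -0.0686 to 0.39, Ddx21 -0.61 to 0.12, Cbx1 -0.0686 to 0.16, Rn7sk -0.59 to 0.15, Rpph1 -0.32 to 0.14, the heat shock list -0.64 to -0.0155, the naive pluripotency list -0.28 to -0.0603, density quartile 3 -0.0352 to -0.00163, Smc3 -0.054 to 0.58, Smc1a -0.081 to 0.50, Igfbp7 -0.40 to 0.0386, Bub1b -1.06 to 0.25, Incenp -0.18 to 0.58, Trim28 -0.13 to 0.58, Ncl -0.15 to 0.43, Eed -0.28 to 0.81, Dnmt1 -0.24 to 0.24, H2afx -0.0552 to 0.42, the ribosome biogenesis list -0.33 to 0.23, density quartile 2 -0.11 to -0.0209, Dnmt3b -1.74 to 0.0599, Utp20 -1.28 to 0.12, Ezh2 -0.39 to 0.14, Mcm6 -1.29 to 0.26, Fau -0.54 to 0.0307. Where the test direction and median of a list differ in sign, the direction is the test's. In the simulation, which had no selection on the outcome, a 2-fold loss was recovered in 1 of 25 features at or below the median count. Above it the loss was recovered in 10 of 25, and the number of libraries was not varied.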

Other observations

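Tests of the strand pattern were chosen after the counts were seen, as was the permutation over features. The tests of shared sequence and of neighbourhoods were set before their results were seen.

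Some features that the lists do not cover held many counts. AY036118 had 60729 and 41096 counts in shGFP and 12843 and 22108 in shNCAPH2, which was 5.27% to 11.96% of the named counts of a library. Lars2, the mitochondrial leucyl-tRNA synthetase, had 3257 counts in shGFP replicate 1 and 244, 227 and 330 in the other libraries.

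Many features with high counts lay opposite another gene. Gm19553, antisense to Pou5f1, had 13940 summed shGFP counts where Pou5f1 had 60, and Gm20628, opposite Hist2h3b, had 56452 where Hist2h3b had 285. Of 243 features with 300 or more summed shGFP counts, 171 (70.4%) had an exon that overlapped an opposite-strand exon, against 465 of 1274 others (36.5%), an odds ratio of 4.13 (Fisher's exact test, two-sided p = 1.90e-22). This measures the pattern that prompted it, so it does not decide whether reads were given to the strand opposite to the transcript, and the labels do not say that the kit marked strand. Counting without strand stays open too. In 17 listed pairs of a coding gene and one annotated as noncoding, the noncoding one had more counts in 10 (exact binomial test, p = 0.63). That test cannot decide the question, as it ignored the size of the differences. The pairs were also not independent, since Gm20628 was paired with both Hist2h2bb and Hist2h3b, and Psph and Cct6a tied at 35 counts. Real antisense transcription was not tested.

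Several abundant features on different chromosomes had counts in nearly one ratio over the 4 libraries. Among pairs of features with 5000 or more summed shGFP counts, 31 were proportional within counting noise, and 9 of these (29.0%) shared a stretch of 50 bases in their transcripts, against 72 of 562 other pairs (12.8%, Fisher's exact test, two-sided p = 0.026; permutation over features, p = 0.013). Reads that align to several places and are counted at each may therefore account for part of the pattern. Shared regulation of separate genes stays open for the pairs without a common stretch, since the share lay between the bounds set for and against it.

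It was also asked whether listed coding genes lie in denser neighbourhoods. The median was 16.0 neighbours for the 1155 listed and 16.0 for the 20600 unlisted coding genes. With a difference of 0 the permutation test of medians could not reject, so it gives no information. Equal medians do not show that the distributions are equal. Among coding genes without an opposite-strand gene the difference of medians was -1.5 (permutation p = 0.093). In the medians there was thus no excess of neighbours for overlap with such genes to explain. Whether loss differs with density cannot be told from these counts, as the densest quartile had a camera adjusted p of 0.10. Expression of the 20600 unlisted genes was not analysed here, so a match on expression was not made.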
